A study of Rattus norvegicus with 4 samples.

How the data were processed

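The series measured messenger RNA in NR8383 cells, an alveolar macrophage line derived from rat lung lavage, that had been exposed for 4 h to carboxyl-functionalized carbon nanotubes (the material NRCWE042) at a nanotube surface of 6.8 cm2 per cm2 of culture. Per the labels' protocols, the cells had been passaged 20 times, were seeded 48 h before, and each array received Cy3-labelled cRNA made from 100 ng of RNA with an integrity number above 7.5. The labels name 4 biological replicates per condition and an unexposed condition. The 4 exposed samples form the 1 group used here, and unexposed samples were not analysed here. No comparison between conditions was therefore made, and nothing below is an effect of the nanotubes. All 4 arrays shared 1 slide and 1 scan; no batch of culture, RNA extraction or labelling was modelled.

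Per the file headers, the deposited values are spot intensities on a linear scale from 1-colour arrays, read by Agilent Feature Extraction 11.0.1.1 (the version is also in the submitters' processing notes). The processed signal used here is background-corrected and spatially detrended within each array, per the file headers, and not normalized between arrays. The raw spot median and local background median were used only for an alternative background correction. The files carry the same layout of 384 spot rows by 164 spot columns, with 45598 sample probes. Most probes have 1 spot, 969 have 2 and 1350 have 10.

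From the processed signal, log2 was taken, spots that the software marked as non-uniform or as population outliers were left out, the spots of a probe were averaged, and each array's 75th percentile over sample probes was subtracted. All levels below are on this scale. No sample spot was saturated. Probes were named through their accession in a RefSeq gene table of the GRCr8 assembly; the file headers name an older build, so no coordinates are given. Of the 45598 probes, 21109 matched and 24489 were left unnamed. The named probes gave 16579 measured genes, of which 3658 had several probes. Such a gene took its brightest probe. A gene was called detected when at least 1 of its probes was marked well above background by the software, on over 50% of its spots, on all 4 arrays. For 962 detected genes, some but not all probes met this. A level sets a gene against the rest of its own array and not against another gene, because probes differ in affinity. Arrays give no read depth, and the number of arrays and the signal over background limit the precision.

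The 26 gene lists, the tests and a rule for the genes named in the text were fixed before the data were examined. The rule took a roster of 32 genes, the 15 detected genes with the largest SD over the 4 arrays, up to 6 members per list (in alphabetical order) that went against the majority of their list, and up to 3 detected members per list with the largest level-adjusted SD together with those among the 5% most variable genes. Of 476 distinct listed genes, 444 were measured, 4 of the listed symbols having been updated through synonyms. The share of a list's measured genes that were detected was set against all other measured genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists, and has an exact binomial 95% interval. Genes are not independent replicates, so these tests describe the lists on these arrays.

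For the spread between replicates, the SD over the 4 arrays was taken per detected gene, and its log2 was adjusted for level with a lowess curve (span 0.3). The median adjusted value of each list with at least 5 detected members was placed among the medians of 10000 random lists of the same size, matched on level in 50 bins, which gave a percentile and a two-sided permutation p, adjusted over 16 lists. The same random lists gave a percentile for each list's shift on each array, where the shift is the median over members of the level minus the gene's own mean over the 4 arrays. A gene deviated on an array when it lay over 1 log2 unit from the median of the other 3. The replicates are separate cultures per the labels; p-values from random lists measure how a list compares with other genes on these 4 arrays.

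The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1. The steps for list spread, list shift and deviating genes were tested on 40 simulated sets of 4 arrays with 7000 genes. A list of 15 genes with doubled SD was found in 39 sets and a list of 15 genes shifted by 0.35 log2 on 1 array in 39 sets, while an unaltered list was called in 4 sets by its SD and in 3 by its shift. Of 200 genes displaced by 1.5 log2 on 1 array, 91.8% were counted as deviating, beside 1.19% of the other genes. The simulated genes varied independently, and a list was called at an unadjusted permutation p below 0.05. On the arrays used here genes varied together and p-values were adjusted over 16 lists, so these rates may not hold for them.

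Alternatives listed before the data were examined were another detection mark of the software (positive and significant signal), detection on at least 3 arrays, detection by all probes of a gene, normexp background correction (offset 50, limma), quantile normalization, scaling on the median of detected probes, genes detected on at least 1 array, the genes in the upper part of the levels (above the median), the mean of a gene's detected probes, and leaving out each replicate in turn. The normexp setting also replaces the detrended signal by raw spot medians, so it changes more than the background. It used the spot medians in place of the spot means named beforehand, which the files do not carry as a column. A further 3 were chosen after seeing the data: leaving out a central area of low signal, the 75th percentile over detected probes (since fewer than 50% of the probes were detected on each array), and scaling on 8 of the 10 spike-in probes, each with 35 spots, that were well above background on every array. The area was found by cutting each array into tiles of 16 by 8 spots and taking the connected tiles around the lowest one whose median lay more than 0.3 log2 below the other arrays.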

Results

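Gene expression was measured on 4 one-colour arrays, each carrying RNA from a separate culture of nanotube-exposed NR8383 rat alveolar macrophages. The design asked how 4 h with the nanotubes alters gene expression relative to unexposed cells; with 1 group analysed here, the data give which genes the exposed cells expressed and how closely the cultures matched. The 75th percentile of the processed signal over sample spots was 734, 757, 595 and 307 on replicates 1 to 4, so the array of replicate 4 was the dimmest. Probes well above background made up 38.8%, 36.8%, 35.3% and 31.1% of the sample probes. Among 308 negative control spots per array, 3 were well above background on replicate 3 and 0 on each of the others.

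Most measured genes of the macrophage, antioxidant, lysosome, unfolded protein and stress response, and cell cycle lists were detected in the exposed cells. Detection does not show that a response was active, and all 13 measured housekeeping genes were detected as well. Of the measured members, 26 of 27 in the NRF2 antioxidant list, 23 of 25 in the lysosome and phagocytosis list, 20 of 20 in the unfolded protein and integrated stress response list and 21 of 22 in the cell cycle list were well above background on all 4 arrays. Detected members included Hmox1, which degrades haem, the lysosomal protease gene Ctsd, the stress-induced transcription factor gene Atf3 and the proliferation marker Mki67. Over all 16579 measured genes, 7363 (44.4%) were detected on all 4 arrays, 1566 on 1 to 3 arrays and 7650 on none. By Fisher's exact test with adjustment over the lists, the shares exceeded those of the other genes for the NRF2 (96.3%, adjusted p = 2.68e-07), lysosome (92.0%, adjusted p = 7.64e-06), stress response (100%, adjusted p = 1.14e-06) and cell cycle (95.5%, adjusted p = 4.28e-06) lists. The single member not detected was Gclm, a subunit of the enzyme that limits glutathione synthesis, in the NRF2 list and Ccne2, detected on 3 arrays, in the cell cycle list. In the lysosome list Ctsk was detected on no array and Mertk on 2. The probes of Ccne2 and Mertk lie in an area of low signal on replicate 3, described further down. Without that area the shares were 100% for the cell cycle and 95.8% for the lysosome list, and without replicate 3 the cell cycle share was 100%.

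Genes of macrophage identity were detected in 24 of 34 cases, a share of 70.6% (95% interval 52.5 to 84.9%) that was higher than in other genes (Fisher's exact test, adjusted p = 0.00661). Cd68, Csf1r, the mannose receptor gene Mrc1 and the transcription factor genes Spi1 and Pparg were among them. The scavenger receptor gene Marco, the F4/80 antigen gene Adgre1, the complement genes C1qa, C1qb and C1qc, the haemoglobin receptor gene Cd163 and the MHC class II invariant chain gene Cd74 were not well above background on any array. Such a reading concerns the probe used, and does not show that the transcript was absent. The list named NF-kB feedback holds regulators of the NF-kB signal together with other NF-kB targets, such as Icam1 and Cd83. Its genes were detected in 13 of 14 cases (92.9%, Fisher's exact test, adjusted p = 0.000927), with Traf1 the exception. The listed genes Nfkbiz, Tnfaip3, Rel and Relb were not measured. In the interferon response list 16 of 20 genes were detected (80.0%, adjusted p = 0.00617 by Fisher's exact test), without Cxcl9, Cxcl11, Ifih1 and Ifit1.

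The cytokine and inflammatory mediator list was split. Tnf, Il1b, Cxcl2, Ccl2 and Ccl3 were detected on all 4 arrays, and Il6, Il10, Il12a, Cxcl1, Ccl20, Csf1, Csf2 and the prostaglandin synthase gene Ptgs2 on none, while the inducible nitric oxide synthase gene Nos2 was detected on 3. In all, 16 of 29 members were detected (55.2%, 95% interval 35.7 to 73.6%), which was not distinguishable from the other genes (Fisher's exact test, adjusted p = 0.314). The inflammasome list had 8 of 11 members detected (adjusted p = 0.0979 by Fisher's exact test; 0.0458 without replicate 4, 0.0473 at 3 of 4 arrays and 0.0427 with all probes detected), among them Nlrp3 and Casp1, while the purinergic receptor gene P2rx7 and the channel gene Panx1 were detected on no array and Nlrp1a on 3. Of the immediate early genes, 15 of 24 were detected (adjusted p = 0.128 by Fisher's exact test). Jun and Jund belonged to these, whereas Fos, Fosb and Egr3 were detected on 1 array each and Egr1, Fosl1 and Klf2 on none. The probes of Egr3 and Ptgs2 lie in the area of low signal on replicate 3. With the software's looser mark of positive and significant signal, 21 of the 24 immediate early genes counted as detected (Fisher's exact test, adjusted p = 0.00422), and the list also passed with all probes of a gene detected (adjusted p = 0.0377).

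Metabolic and damage-response lists also lay above the other genes. Sterol and lipid handling had 16 of 20 members detected (adjusted p = 0.00617, Fisher's exact test), without the cholesterol exporter gene Abca1, Apoe, Fasn and Scd. Glycolysis and hypoxia had 15 of 18 (adjusted p = 0.004 by Fisher's exact test), without Egln3, Hk1 and Vegfa. The heat shock and metallothionein list had 10 of 13 and the p53 and DNA damage list 14 of 20 (both adjusted p = 0.0419, Fisher's exact test). Hspa1a, the inducible HSP70 gene, and Mt3 were detected on no array and Hsph1 on 3. In the p53 list Btg2, Plk2, Pmaip1, Rrm2b and Zmat3 were detected on none and Xpc on 3. The probe of Zmat3 lies in the area of low signal on replicate 3. Under the looser mark of positive and significant signal, the heat shock (adjusted p = 0.0728) and p53 (adjusted p = 0.155) lists no longer passed Fisher's exact test. All 13 measured housekeeping genes were detected (adjusted p = 0.000135 by Fisher's exact test). Matrix remodelling and fibrosis mediators had 7 of 20 (35.0%, adjusted p = 0.543 by Fisher's exact test), among them Mmp12, Mmp9, Tgfb1, Igf1, Plaur and Tgm2, while the osteopontin gene Spp1 was not well above background on any array.

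Markers of other cell types were mostly not detected. Detected shares were 1 of 17 for lung epithelium (adjusted p = 0.00337), 1 of 13 for fibroblast and smooth muscle (adjusted p = 0.0183), 1 of 11 for neutrophil (adjusted p = 0.0438), 0 of 9 for mast cell and basophil (adjusted p = 0.0124, interval up to 33.6%) and 4 of 21 for brain, liver, pancreas and heart (adjusted p = 0.0419), all lower than in the other genes by Fisher's exact test. The neutrophil call and that for brain, liver, pancreas and heart ended when every probe of a gene had to be detected (adjusted p = 0.087 and 0.102, Fisher's exact test), and the mast cell call ended at 3 of 4 arrays (adjusted p = 0.055, Fisher's exact test) and without replicate 4 (0.0559). The exceptions were the cilia gene Foxj1, the proteoglycan gene Dcn (3.41 ± 0.28; levels here and below are log2 relative to the array's 75th percentile, ± SD over n = 4 arrays), the antimicrobial peptide gene Camp (2.64 ± 0.04), the elastase gene Cela1 (6.76 ± 0.10), Cpa1, Mbp and Tnnt2. T and NK cell genes (3 of 16, adjusted p = 0.0641, and 0.0358 without replicate 4), B cell genes (3 of 8, adjusted p = 1), endothelial genes (4 of 10, adjusted p = 1), erythroid genes (2 of 8, adjusted p = 0.354) and Y-linked genes (0 of 3, adjusted p = 0.314) did not pass Fisher's exact test. Detected members of these were Cd3d, Il7r and Lck, then Ebf1, Fcrla (4.93 ± 0.24) and Pax5, then Cdh5, Flt1, Pecam1 and the von Willebrand factor gene Vwf (5.50 ± 0.29), and Epor and Hba-a1.

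**Figure D1:**
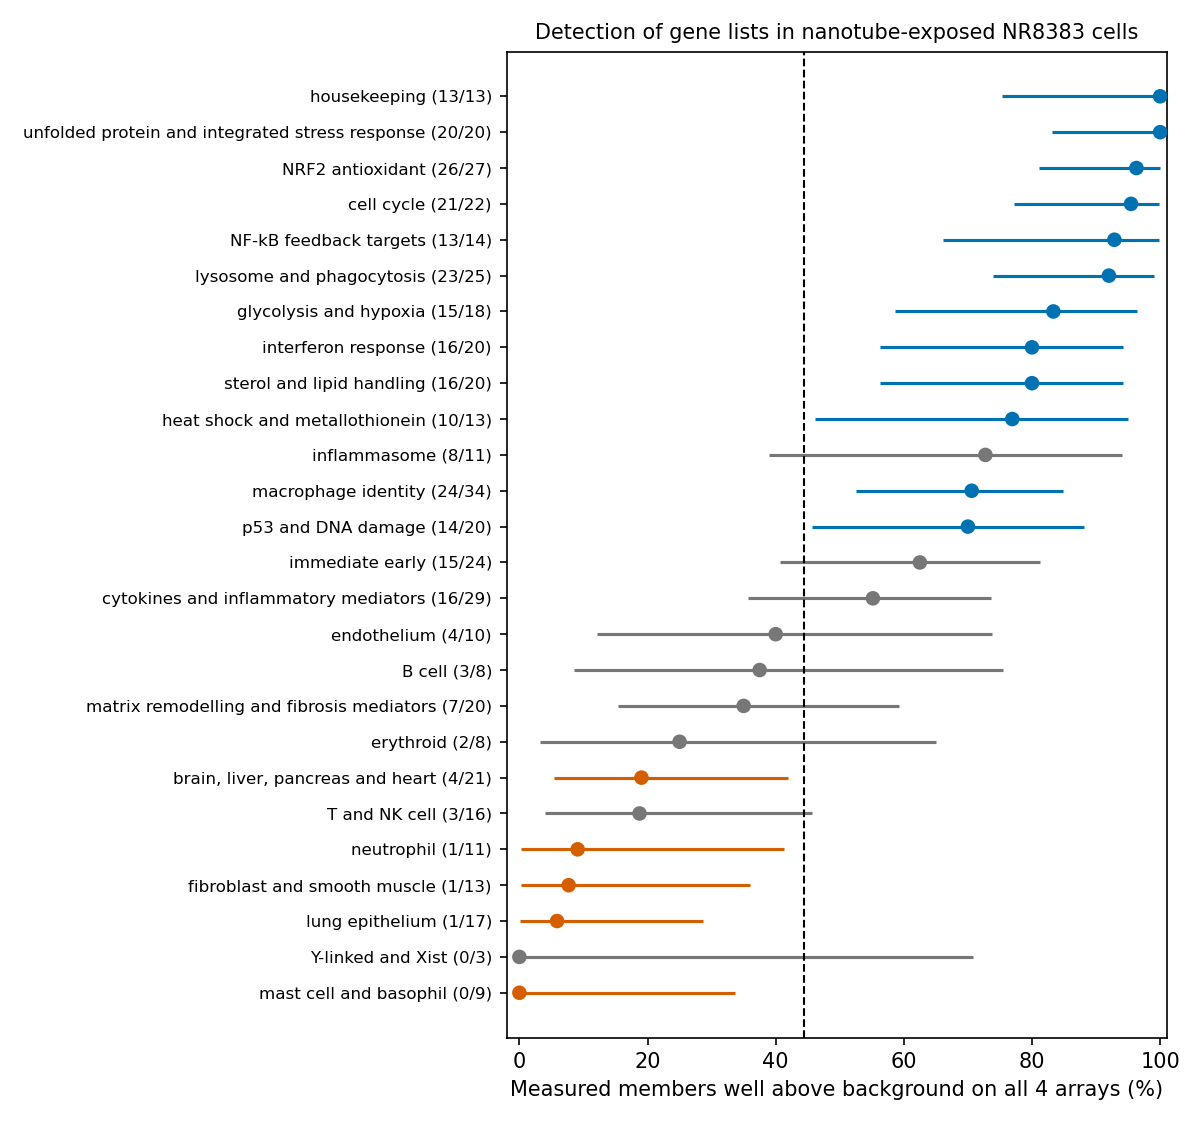
Share of each list's measured genes that were well above background on all 4 arrays (x axis, %), with exact 95% binomial intervals and the counts beside each name. The dashed line is the share over all measured genes, 44.4%; blue lists lay above and orange lists below the other genes after adjustment, and grey lists did not pass.

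The roster genes that were detected had levels whose replicate SD was mostly below 0.5. Among macrophage genes, Cd68 lay at 7.47 ± 0.24, Csf1r at 0.96 ± 0.10, Mrc1 at 0.99 ± 0.42, Spi1 at 3.73 ± 0.51 and Pparg at 6.11 ± 0.07. The mediators Tnf (6.64 ± 0.48), Il1b (6.39 ± 0.11), Cxcl2 (2.70 ± 0.29), Ccl2 (6.91 ± 0.19) and Ccl3 (9.05 ± 0.33) were followed by Nfkbia, the NF-kB inhibitor gene, at 4.81 ± 0.55 and Nlrp3 at 0.85 ± 0.22. Of the antioxidant and metal-response genes, Hmox1 lay at 7.07 ± 0.24, Srxn1 at 6.70 ± 0.16, Nqo1 at 1.68 ± 0.21 and Mt2A at 0.48 ± 0.26. Stress and damage genes were Atf3 at 5.47 ± 0.15, the cell cycle inhibitor gene Cdkn1a at 5.67 ± 0.60, Gadd45a at 2.87 ± 0.22 and Ddit3 at 4.85 ± 1.57. The wide SD of Ddit3 came from replicate 3 (2.54, against 5.85, 5.84 and 5.17), where its probe lies inside an area of low signal on that array, described further down. Ctsd lay at 9.22 ± 0.26, the macrophage elastase gene Mmp12 at 3.29 ± 0.18 and Mki67 at 2.84 ± 0.14. These levels sit on each gene's own probe scale and give no order between genes.

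**Figure D2:**
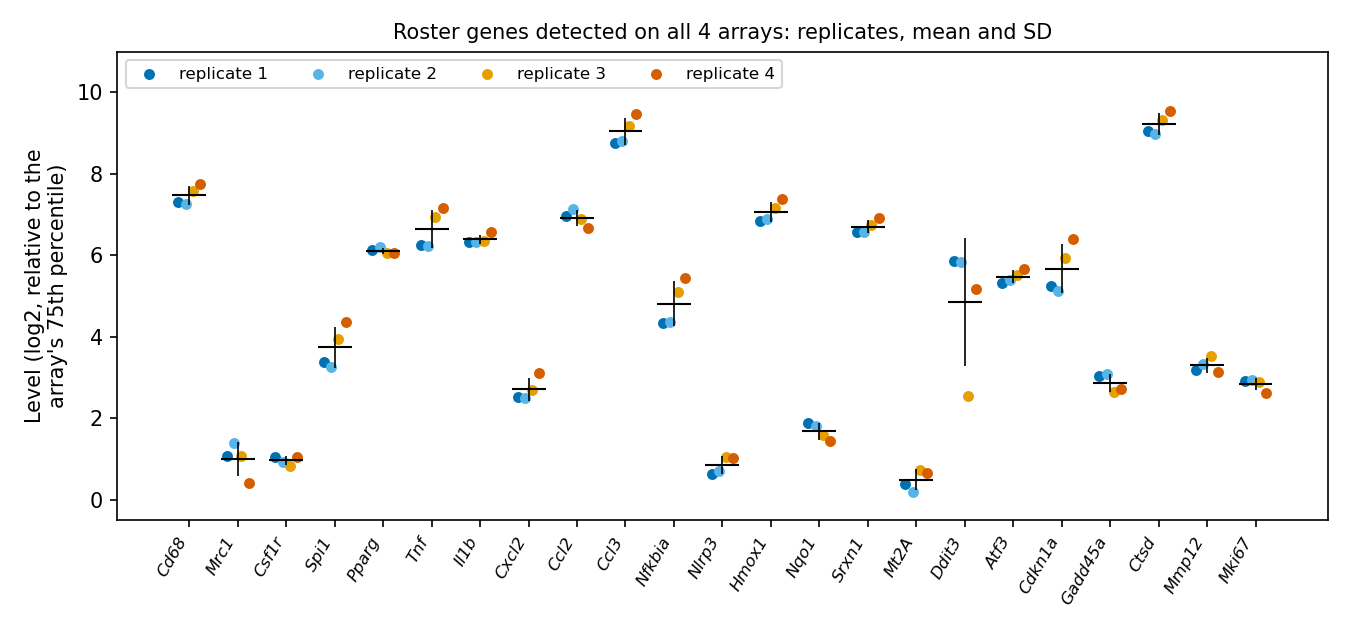
Levels of the roster genes detected on all 4 arrays (y axis, log2 relative to the array's 75th percentile), with coloured points for replicates 1 to 4, a horizontal bar at the mean and a vertical bar of 1 SD each way. Pparg has the narrow SD of 0.07 and Ddit3 the wide SD of 1.57, with replicate 3 at 2.54.

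Genes of NF-kB feedback and immediate early genes were low on replicates 1 and 2 and high on replicates 3 and 4, relative to their own means. The NF-kB feedback list shifted by -0.30, -0.41, 0.25 and 0.45 log2 units on replicates 1 to 4, and the immediate early list by -0.35, -0.34, 0.27 and 0.44; with spike-in scaling the shifts themselves became 0.14, 0.16, 0.09 and -0.40 for NF-kB feedback and 0.10, 0.23, 0.11 and -0.41 for immediate early. That scaling moved the median of all detected genes to 0.38, 0.50, -0.10 and -0.75 on the 4 arrays, and relative to these medians the NF-kB shifts were -0.24, -0.34, 0.19 and 0.35. Under normexp they were -0.15, -0.21, 0.26 and 0.12 for NF-kB feedback and -0.20, -0.16, 0.26 and 0.11 for immediate early genes. The shift on replicate 4 was thus much smaller, but there every other list except p53 (0.02) was negative, down to -0.34 for cell cycle genes. Over all settings, the percentiles of NF-kB feedback and immediate early genes among matched lists on replicate 4 were 96.8 or higher. Without replicate 4, replicates 1 to 3 read -0.14, -0.24 and 0.40 for NF-kB feedback and -0.22, -0.17 and 0.42 for immediate early genes. On replicate 3 the NF-kB shift was 0.13 without replicate 1 and 0.11 without replicate 2, and the immediate early shift was 0.18 without replicate 1. Of the 15 detected immediate early genes, 0 lay above their own mean on replicate 1 or 2, 14 did on replicate 3 and 15 on replicate 4. Of the 13 NF-kB feedback genes 1, 3, 11 and 10 did on replicates 1 to 4. Over all detected genes the shares were 38.7%, 41.9%, 61.9% and 59.6%. The first principal component of all detected genes, centred per gene, held 78.4% of the variance (86.9% without the area of low signal), with loadings of -0.44, -0.54, 0.39 and 0.60 on replicates 1 to 4. Jund, which encodes an AP-1 subunit, read 5.48, 5.42, 6.56 and 7.03, and Jun read 2.62, 2.63, 3.66 and 3.73. Among the NF-kB genes, Nfkbia read 4.34, 4.36, 5.08 and 5.44, the ribonuclease gene Zc3h12a 1.04, 0.91, 1.69 and 2.10, and Bcl3 0.94, 0.87, 1.70 and 2.00.

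Among random lists matched on level, the NF-kB shifts stood at percentiles 0.28, 0.07, 99.9 and 99.8 and the immediate early shifts at 0.01, 0.35, 99.9 and 99.9 on replicates 1 to 4. Over all 16 lists and 4 arrays, 9 of 64 shifts lay outside the central 95%, where 3.2 would by chance. Of these, 8 belonged to these 2 lists and 1 to sterol and lipid handling on replicate 3 (0.20, percentile 99.2). The direction was not particular to the 2 lists. Among the gene families described further down, 139 Slc genes shifted by -0.19, -0.22, 0.16 and 0.30 on replicates 1 to 4. The 22 Map genes shifted by -0.28, -0.26, 0.20 and 0.31, while Clec (-0.37) and Vom genes (-0.24), among others, were lower on replicate 4. No percentile was computed for the shifts of families. The shifts on 4 arrays sum to about 0 for each gene and are not independent, and each array is 1 culture, so this is a description without a test of a condition. On the same arrays the ratio of sample signal to spike-in signal, relative to replicate 1, was 0.12, -0.61 and -1.30 log2 units on replicates 2, 3 and 4. The spike-in signal itself differed by -0.08, 0.23 and -0.09, and the 75th percentile of the sample probes by 0.03, -0.38 and -1.38. The low signal of replicate 4 thus lay in the sample probes and not in the spike-ins.

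**Figure D3:**
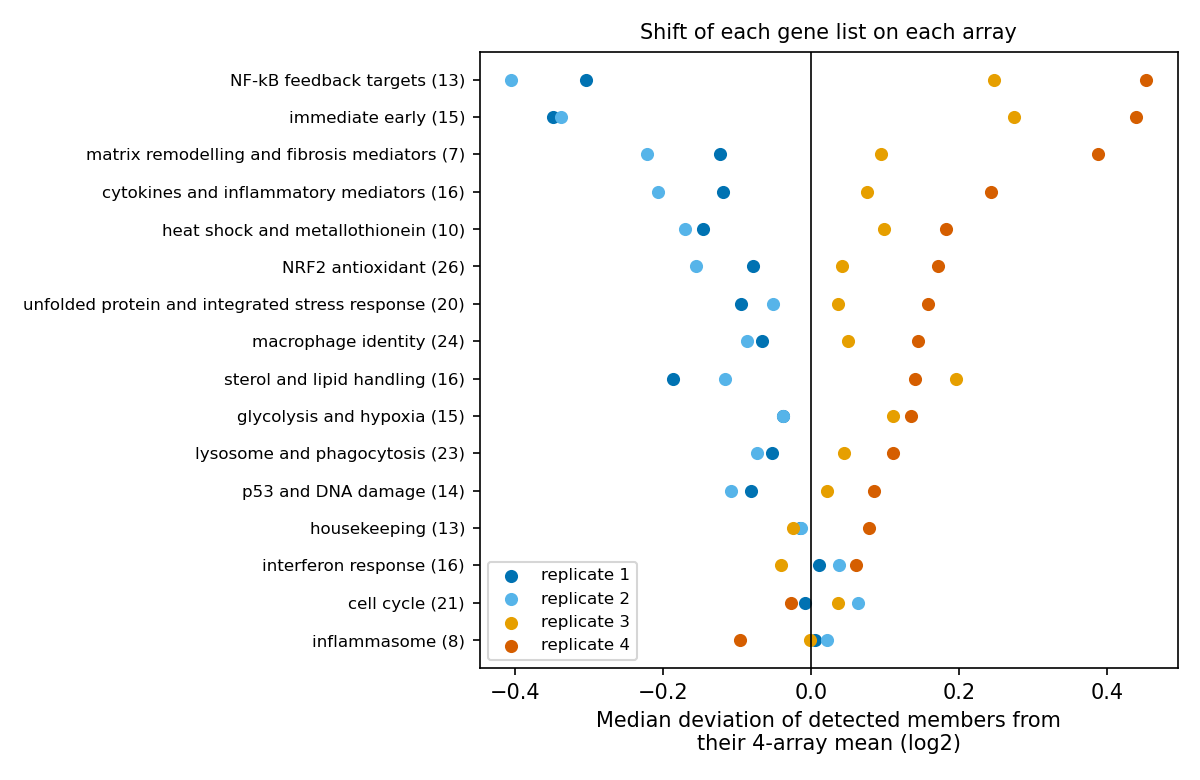
Shift of each list on each array: the median over detected members (number in parentheses) of the level minus the gene's mean over the 4 arrays (x axis, log2), with coloured points for replicates 1 to 4. NF-kB feedback and immediate early genes span from -0.41 to 0.45 and from -0.35 to 0.44, and the housekeeping list from -0.02 to 0.08; under spike-in scaling the shifts on replicates 1 and 4 are 0.14 and -0.40 for NF-kB feedback, 0.10 and -0.41 for immediate early and 0.43 and -0.77 for housekeeping genes, and under normexp the housekeeping shifts are 0.08 and -0.28.

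As for the spread between cultures, the NF-kB feedback list had a median SD of 0.43 over its 13 detected members (percentile 99.7 among matched lists) and the immediate early list 0.42 over 15 (percentile 99.6). Neither passed after adjustment over the 16 lists (permutation p = 0.0068 and 0.0084, adjusted p = 0.0672 for both), and with spike-in scaling both fell to the other end (percentiles 0.04 and 0.07). Under normexp neither list stood out (percentiles 46.1 and 55.5). No list was more or less variable than matched genes at an adjusted p of 0.05, and only these 2 had an unadjusted permutation p below it. Without replicate 4, which was the dimmest array, 3 lists passed: NF-kB feedback was more variable (percentile 99.8), and the cell cycle (0.15) and inflammasome (0.30) lists were less variable, each with an adjusted permutation p of 0.0331. Percentiles of the other lists were 95.2 for macrophage identity, 94.0 for the unfolded protein and integrated stress response, 82.5 for matrix remodelling, 82.1 for cytokines, 79.6 for glycolysis, 49.8 for sterol and lipid handling, 49.6 for p53, 44.3 for heat shock, 33.8 for lysosome, 29.2 for interferon, 20.5 for NRF2, 15.7 for housekeeping, 12.2 for inflammasome and 4.51 for cell cycle genes. The stress response value fell to 7.18 without the area of low signal that holds the probe of Ddit3.

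Members with wide spread within their lists included Cebpb (7.77 ± 0.67), a transcription factor gene of macrophages, the metallothionein gene Mt1 (5.08 ± 0.57), Trib3 (5.41 ± 0.57), Hsp90b1 (2.89 ± 0.64), Tgfb1 (2.77 ± 0.57), Cdkn1a, Jun and Jund, all among the 369 most variable genes. So was Gapdh (9.67 ± 0.61), which is often used as a reference gene. Mx2, an antiviral GTPase gene, read 4.94, 4.86, 3.66 and 4.80, with its probe in the area of low signal. No list was over-represented among the most variable genes by Fisher's exact test (0 of 16 lists at an adjusted p of 0.05, and 0 at an unadjusted one). Over all detected genes the median SD was 0.25 (0.20 without replicate 4) and 11.6% had an SD above 0.5 (16.6% without replicate 3, 5.57% without replicate 4). With spike-in scaling the median SD was 0.58 and 59.8% lay above 0.5, and under normexp 7.01% did. At the median of 0.25, a mean over 4 cultures has a 95% interval of 0.40 log2 units each way, or 1.32-fold.

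The largest SDs belonged to genes that were low on replicate 3. All 15 genes with the largest SD (Nr2c2ap, Wfdc21, Cebpg, Hsd17b11, Rfxank, Slc52a2, Naa20, Naa80, Cars1, Ppp1r10, Slc15a4, Gpr89b, Ddit3, Chmp1b and Socs5) have their probe in the central area of low signal. Nr2c2ap read 5.14, 5.13, 0.48 and 4.61, and Cebpg, a partner of other C/EBP factors, read 4.50, 4.62, 0.14 and 3.05. The area spans spot rows 145 to 256 and spot columns 65 to 96, holds 4.23% of the sample spots, and its lowest tile on replicate 3 lay at -3.58 log2 units against the other arrays (-0.82 on replicate 4). Of the 130 genes lower on replicate 3, 116 (89.2%) have their probe there, beside 3.11% of all detected genes, in part because the area was drawn where signal was low. Without the area 10 genes were lower on that replicate.

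**Figure D4:**
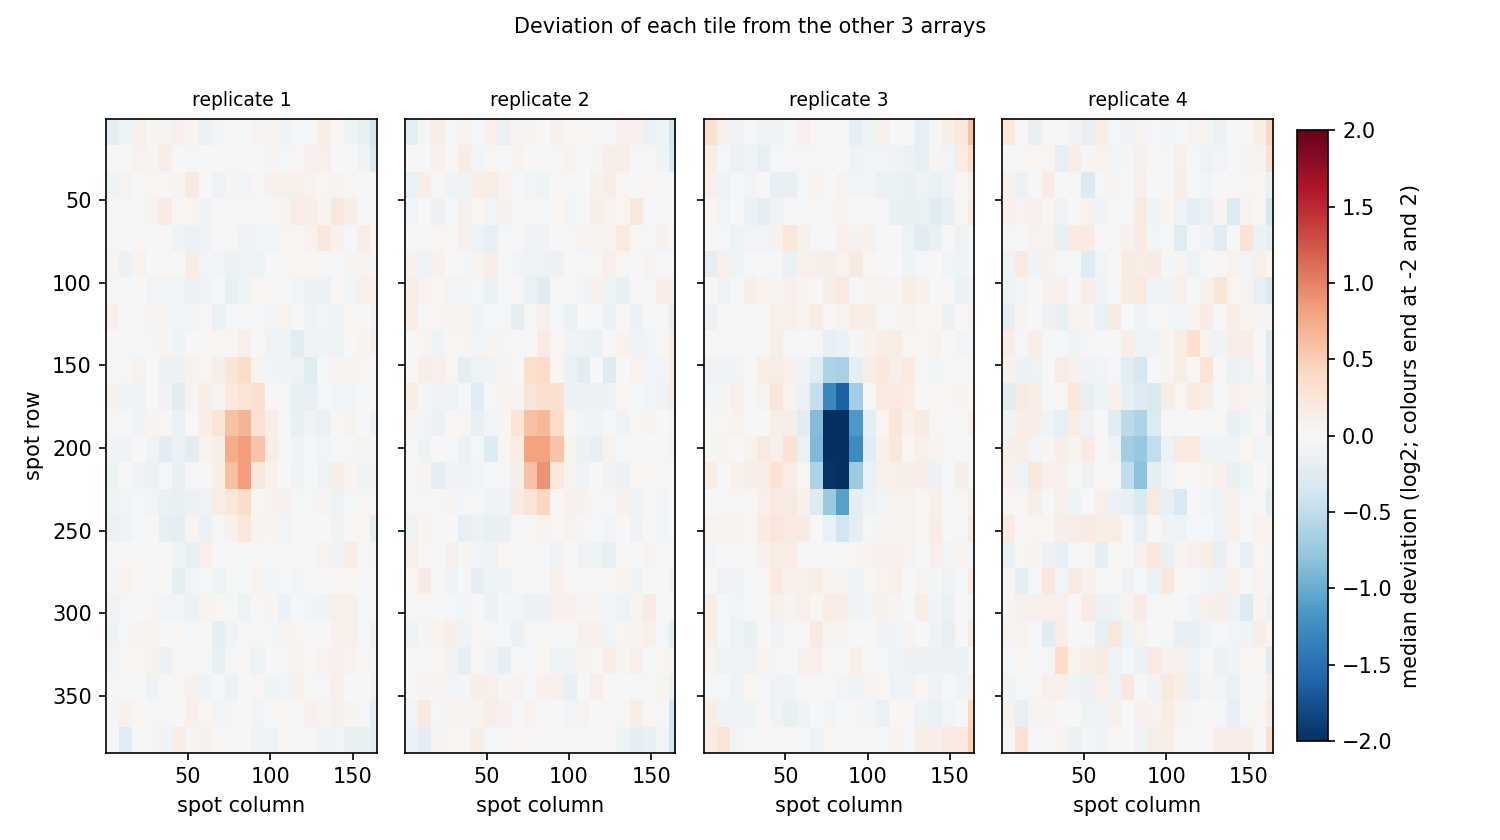
Map of the 4 arrays in tiles of 16 by 8 spots (axes, spot column and spot row); the colour is each tile's median deviation from the median of the other 3 arrays (log2). The blue centre on replicate 3 reaches -3.58 and that on replicate 4 reaches -0.82, and the red centres on replicates 1 and 2 follow from them, since each array is set against the others.

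Outside that area, and chosen after its values were seen, the interferon-induced GTPase gene Ifi47 had the largest SD (3.44, 1.13, 0.64 and 0.45 on replicates 1 to 4). Others with a wide SD there were Cttnbp2nl (2.68, 2.73, 2.46 and 0.68) and the kinase-like gene Trib1 (-1.84, -2.17, -0.56 and -0.35). Counted over all detected genes, 28 were higher and 55 lower on replicate 1, 42 and 84 on replicate 2, 35 and 130 on replicate 3, and 418 and 92 on replicate 4. Without the area these counts were 6 and 32, 11 and 51, 19 and 10, and 383 and 73. The direction of most calls depended on the setting, on replicate 3 through the area. Under normexp 130 were higher and 5 lower on replicate 1, 163 and 8 on replicate 2, and 7 and 348 on replicate 4. With the 75th percentile over detected probes these were 44 and 20, 61 and 35, and 168 and 175. Quantile normalization gave 226 and 125 on replicate 4. The count higher on replicate 4 was 104 without replicate 1 and 81 without replicate 2. Leaving out replicate 2 gave 97 higher and 181 lower on replicate 1 and leaving out replicate 1 gave 119 and 296 on replicate 2. Leaving out replicate 4 turned the direction, with 45 higher and 4 lower on replicate 1 and 57 and 9 on replicate 2. On replicate 3, 67 genes were higher without replicate 4.

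Replicates 1 and 2 lay closest together. The SD of the gene-wise difference was 0.16 log2 units between them, with 7 genes over 1 log2 unit apart, against 0.36 to 0.61 for the other 5 pairs. Over 1014 probes with 10 spots, the difference between replicates 1 and 2 had an SD of 0.076, which is 3.1 times what the scatter between spots gives (0.025). Spot scatter leaves out labelling and hybridisation, so this ratio does not tell 2 cultures from 1; the labels name them as separate replicates. For the same probes the median SD was 0.066 between spots of 1 array (0.058 without replicate 3) and 0.20 between arrays (0.15 without replicate 4).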

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

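The test of the scaling percentile, and the reading of normexp beside the level of genes higher on replicate 4, were chosen only after the result was seen; those of spots inside the area, of second probes outside it and of the level of genes higher on replicate 4 were written down before their values were computed. In 102 sets of 4 values (array summaries, list shifts and named genes), 11 had 1 array far from the other 3 by Dixon's ratio (its gap to the nearest value over the whole range). Of these, 7 came from the 14 genes picked for their large SD. Among the 88 other sets 4 did, but 44 of the 88 were list members also picked for a wide spread. The rate of about 1 in 20 that chance gives is therefore no yardstick for them.

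On replicate 3, the low values of Nr2c2ap (ratio 0.886), Rfxank (0.860), Slc52a2 (0.862), Naa80 (0.951), Cars1 (0.860), Ppp1r10 (0.960), Slc15a4 (0.845) and Mx2 (0.888) stood apart from the other arrays. Each has its probe in the central area of low signal, and a candidate explanation is a loss of signal there. In 54 probes with spots both inside and outside the area, the inside spots were lower on replicate 3 by a median of -0.54 log2 units relative to replicates 1 and 2, in 47 of the 54. The area was drawn where signal was low, with these spots included, so a lower reading inside was in part fixed by that choice. A lower transcript level in culture 3 would lower other probes of the same genes too; for the 16 of 116 genes with another probe outside the area, that probe deviated by a median of 0.039 on replicate 3 (quartiles -0.13 and 0.22), against -1.73 inside, which argues against it for these 16. The other genes in the area were not tested in this way, and no biological explanation was tested, since the design gives no group to set replicate 3 against.

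The level of Il1b (ratio 0.875, read 6.56 on replicate 4), that of the ferritin light chain gene Ftl1 (0.907, read 11.78) and the shift of the housekeeping list (0.890) set replicate 4 apart from the others. The housekeeping shifts were small (-0.02, -0.01, -0.02 and 0.08). On replicate 4 the shift lay below the median deviation of all detected genes (0.10). It became -0.19 there under quantile normalization and -0.28 under normexp.

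A second pattern is the 418 genes higher on replicate 4. Background handling on this dim array remains a possible explanation: the median level of these genes lay at percentile 56.1 of the detected genes, so they are not only the dimmest, but the normexp setting gave 7 genes higher and 348 lower. That setting also dropped the detrending, used raw spot medians and added an offset, so it does not single out the background, and level alone was too narrow a bound to exclude it. The percentile used for scaling may account for the excess over lower genes, since with the 75th percentile over detected probes 168 genes were higher and 175 lower. That count still exceeded the numbers higher on replicates 1 to 3 under the same scaling (44, 61 and 14), and why was not tested. The detection filter itself favours weak genes that read higher on replicate 4. The lowest probe level marked well above background was -2.56, -2.41, -2.09 and -1.24 on replicates 1 to 4. A weak gene thus had to read higher on replicate 4 to be counted. Among genes above the median level, counted further down, more were still higher than lower on replicate 4.

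Signals outside the report's lists were of 2 kinds. Of 13440 external RNA control (ERCC) spots over the 4 arrays, 311 (2.31%) were well above background, against 3 of 1232 negative control spots (0.244%). Of the 96 control probes, 2 held 184 of the 311, and the others came to 127 of 13160 (0.965%). The 311 were unevenly spread, with 130, 59, 74 and 48 on replicates 1 to 4. Probes without a gene name numbered 4958 among those detected on all 4 arrays.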

How the results depend on the processing

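The area of low signal, the 75th percentile over detected probes and spike-in scaling were chosen after seeing the data. The number of detected genes stayed within 1.5 times of 7363 under all 8 alternatives run for it, and the number of lists detected above the other genes did as well, while lists below numbered 3 when all probes of a gene had to be detected. No list was over-represented among the most variable genes under any of the 12 alternatives. Where a value moved, the cause was not tested unless stated.

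The median SD was 0.58 with spike-in scaling and 0.197 to 0.269 with 1 replicate left out. The share of genes with an SD over 0.5 was 7.01% under normexp, 18.9% for genes detected on at least 1 array, 59.8% with spike-in scaling and 5.57 to 16.6% with 1 replicate left out. Lists more variable numbered 0 to 1 and lists less variable 0 to 2 with 1 replicate left out. The spread percentile of NF-kB feedback was 46.1 under normexp and 0.04 with spike-in scaling, and that of immediate early genes 55.5 and 0.07, which sets the arrays far apart for all genes. Over all settings but spike-in scaling the adjusted permutation p was 0.0331 to 0.94 for NF-kB feedback and 0.0512 to 0.94 for immediate early genes. With spike-in scaling the list shifts on replicates 1, 2 and 4 reversed to 0.14, 0.16 and -0.40 for NF-kB feedback and to 0.10, 0.23 and -0.41 for immediate early genes, while their percentiles among matched lists cannot change with a scaling that moves all genes of an array alike; over all settings these ranged from 98.3 to 100 on replicate 3 and 96.8 to 100 on replicate 4. Under normexp the shifts on replicate 4 moved to 0.12 for NF-kB feedback and 0.11 for immediate early genes. With 1 replicate left out the shifts on replicates 1 to 4 ranged from -0.45 to -0.14, -0.51 to -0.24, 0.11 to 0.40 and 0.32 to 0.54 for NF-kB feedback, and from -0.46 to -0.22, -0.45 to -0.17, 0.18 to 0.42 and 0.31 to 0.55 for immediate early genes. Under normexp the spot SD was 0.0973 and the array SD 0.269; with 1 replicate left out they were 0.0581 to 0.0711 and 0.152 to 0.225.

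Genes higher and lower on replicates 1 to 4 were, under normexp, 130 and 5, 163 and 8, 5 and 209, and 7 and 348. Under quantile normalization they were 34 and 38, 50 and 53, 22 and 143, and 226 and 125. Scaling on the median of detected probes gave 34 and 32, 49 and 57, 23 and 138, and 280 and 124. The 75th percentile over detected probes gave 44 and 20, 61 and 35, 14 and 146, and 168 and 175. Spike-in scaling gave 699 and 2, 1420 and 1, 2 and 689, and 1 and 4193. Genes detected on at least 1 array gave 291 and 156, 171 and 262, 121 and 332, and 581 and 327. Genes above the median level gave 10 and 15, 13 and 25, 10 and 62, and 230 and 24. Without the area the counts were 6 and 32, 11 and 51, 19 and 10, and 383 and 73. With another replicate left out they ranged from 2 to 97 higher and 4 to 181 lower on replicate 1, 6 to 119 and 9 to 296 on replicate 2, 1 to 67 and 109 to 142 on replicate 3, and 81 to 551 and 12 to 130 on replicate 4. Replicate 4 had the lowest signal over background, which limits the genes called detected on all arrays, 7902 without it. No paired analysis was possible because there is 1 group.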

Other observations

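The tests of gene families, of members inside the area, of a bias that depends on level and of yield were chosen only after the result was seen. Genes whose symbols share a stem were looked at after the data were examined, as 32 families with at least 30 measured members. Most genes with the symbol stems of ribosomal protein, translation factor and RNA polymerase genes were detected. All 42 mitochondrial ribosomal Mrpl genes, 50 of 53 Rpl, 36 of 42 Rps, 45 of 48 Eif and 25 of 30 Polr genes were well above background on all 4 arrays (Fisher's exact test over the families, adjusted p = 4.7e-14, 9.81e-14, 1.63e-07, 2.75e-12 and 4.6e-05). A shared stem, such as Rps, can also take in genes that do not encode ribosomal proteins. Families of sensory and barrier genes were rarely detected: 1 of 55 olfactory receptor Olr genes, 0 of 36 taste receptor Tas genes, 1 of 37 defensin Defb genes and 5 of 47 keratin Krt genes (adjusted p = 2.75e-12, 4.5e-09, 5.63e-08 and 2.65e-06 by Fisher's exact test). Of the vomeronasal receptor Vom genes, 14 of 122 were detected (adjusted p = 7.32e-14 by Fisher's exact test). Cytochrome P450 genes had 9 of 70 detected. In all, 14 families lay above and 8 below the other genes.

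For their level, solute carrier (Slc) genes had a wide spread between cultures, at percentile 99.9 of level-matched lists over 139 detected members (permutation p = 0.002, adjusted p = 0.056), and did not pass the adjustment; their median SD of 0.34 was below that of Cyp genes (0.43). At the other end, Rpl genes stood at percentile 0.48 (permutation p = 0.0098, adjusted p = 0.137). No family passed.

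A further pattern, the joint shift of NF-kB feedback and immediate early genes, was weighed with 3 technical explanations. Low signal in the centre of replicate 3 is argued against, because only 1 of the 28 detected members of the lists (3.57%) has its probe there, and a bias that depends on level is argued against as the whole cause by a range of 0.67 after quantile normalization, from 0.86 as reported. The range was 0.48 under normexp. That setting changes background, signal and detrending together, so the part of background, signal or detrending in the pattern was not tested. A different yield of sample RNA relative to the spike-ins remains a possible explanation, since replicate 4 had a ratio -1.30 log2 units from replicate 1. The arrays' order by yield was the exact reverse of that by NF-kB shift as reported. Such a reverse, or the same order, was the outcome set down for yield as the cause. It was not seen under normexp or for immediate early genes. Since 4 arrays cannot test an order, yield and a difference between the cultures cannot be told apart. No biological explanation was tested, since all 4 cultures belong to 1 group.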
